A study of Xenopus laevis with 2 samples.

How the data were processed

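Total RNA from dorsal posterior pieces of stage 18 embryos was extracted with Trizol, and 6 µg was used to make biotin-labelled cRNA for the Affymetrix Xenopus laevis array, per the labels' protocols. The depleted embryos received 2 ng of morpholino in the dorsal blastomeres at the 4-cell stage together with GFP, used to check where the injection went, per the labels' protocols. Whether the wildtype embryos were injected with anything is not given in the sources used here. Each group had 1 array, grouped by its title in the labels.

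The deposited values were probe set intensities on a linear scale made with MAS5, per the submitters' processing notes. The MAS5 version, the scaling target and detection calls are not given in the sources used here. MAS5 summarises perfect-match probes against mismatch probes and is noisy at low signals, so dim probe sets have less certain ratios.

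The table held 15611 probe sets, of which 120 Affymetrix control probe sets were left out of the comparison. Genes were named from the platform annotation table: 9304 probe sets had exactly 1 gene symbol, 195 had several and 5992 had none. Of the 9304, 9227 were matched by Entrez ID to the gene table of the Xenopus_laevis_v10.1 assembly, and 2 symbols were updated. No gene was named from a probe set with several symbols, including 158 probe sets that name both homeologs of a gene. Xenopus laevis is allotetraploid, and the suffixes .L and .S mark the copies from its long and short subgenomes, which were treated as separate genes. Signal from near-identical copies can be shared between their probe sets.

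Signals below 19.7, the 25th percentile of both arrays, were raised to it, and values were turned to log2. The 7747 probe sets whose mean signal was at or above the median, 75.0, were kept, and the log2 ratio was centred on its median, which moved it by 0.0089. No kept probe set was at the floor. A gene's value was the mean over its kept probe sets, giving 4543 genes, 580 of them with more than 1 probe set. With no replicates, a probe set or gene was counted as higher or lower by a fixed rule of size, 2-fold or more. For each of 25 gene lists, the median of the measured members was placed among the medians of 10000 random lists of the same size matched on mean log2 signal in 20 bins. Percentiles at or under 2.5 and at or above 97.5 are called tails and describe these arrays only. Lists with fewer than 4 measured genes got no percentile. The Wnt list holds tcf3 through an older alias of tcf7l1, although the current symbol tcf3 belongs to another transcription factor. Lists share some genes, and members of a list are not independent.

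The rule for the genes to name, the lists, and all alternatives except those said to be added were fixed before the data were examined. The rule took the targeted gene, up to 12 highest and 12 lowest genes past 2-fold with a symbol that is not a clone name, up to 4 members of each list with the largest size of ratio, list members past 2-fold, and a set of marker genes. Only 10 lower genes met it. The text gives part of the list members and markers. The lectin gene itln1.L, the homeologs ag1.L, foxa4.L and ctnnb1.L, and ripply2.2.S were outside the rule and chosen after their values were seen.

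The alternatives were no floor, a floor at the 40th percentile, an added offset in place of the floor, no centring, quantile normalization, loess on mean signal, no filter, a filter at the 75th percentile, thresholds of 1.5-fold and 3-fold, a gene's brightest probe set, and list means. List members matched also by synonym, and probe sets naming both homeologs counted as 1 gene, were added after the data were seen. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

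The procedure was tested on simulated arrays built for this comparison, with 7746 kept probe sets. It called 93% of changes of 1.5 on the log2 scale and 100% of changes of 2.5 in the right direction, and called 11 of 7509 unchanged probe sets. The simulated noise was normal, with the robust spread of the log2 ratio between these same arrays at each signal level. The 11 calls therefore do not measure error between embryos or dissections. A simulated list shifted by 0.3 reached percentile 99.79, and an unshifted one 84.87.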

Results

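The series profiled dorsal posterior pieces of Xenopus laevis neurulae, which the labels describe as mostly mesoderm, on an Affymetrix Xenopus laevis expression array. Derriere (gdf3) is a secreted ligand of the TGF-beta superfamily that acts in mesoderm formation and posterior patterning. By the labels, one group was wildtype and the other was depleted of Derriere with 2 ng of antisense morpholino, a synthetic oligonucleotide that blocks translation or splicing of its target, placed at the 4-cell stage. Both groups were dissected at stage 18. Each condition had 1 array, so no difference below has a replicate check and no p-value is given. The number of arrays limits the precision. The series was made to find genes that depend on Derriere in posterior mesoderm, and the comparison asked which transcripts differed between the arrays.

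The median signal over 15491 probe sets was 75.4 in the array labelled wildtype and 74.1 in the array labelled Derriere depleted. Over the 7747 probe sets kept for the comparison, the log signals of the arrays had a Pearson r of 0.977 and a Spearman rho of 0.970 across probe sets, which are not independent replicates. The SD of the log2 ratio over these probe sets was 0.330. Different probe sets of 1 gene, measured on the same RNA, had a pooled SD of 0.228 over 580 genes, which covers technical error of the array and not the spread between embryos.

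The targeted transcript was higher in the array labelled Derriere depleted. The single probe set for derriere, gdf3.S, read 552.0 in the array labelled wildtype and 2318.6 in the array labelled Derriere depleted, a log2 ratio of 2.06 or 4.17-fold. A morpholino need not lower the transcript it targets, so this value does not decide whether the labels are right, but it runs against what the label alone would lead one to look for. Every direction below is therefore given for "the array labelled Derriere depleted" over "the array labelled wildtype", and would turn around if the labels were exchanged.

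Few transcripts differed by 2-fold or more, and the differences in the higher direction were larger. In the array labelled Derriere depleted, 17 of 4543 genes were at least 2-fold higher and 11 were at least 2-fold lower. Among probe sets, 27 of 7747 were at least 2-fold higher and 21 lower, 7 were at least 4-fold higher and 0 were at least 4-fold lower. The count of lower probe sets was 7 when a constant was added to all signals in place of the floor, and with no filter on low signals 55 were higher and 81 lower. With the kept probe sets ranked by mean signal into 4 equal bins, 24 of the 48 probe sets past 2-fold lay in the lowest bin and 4 in the highest.

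**Figure D1:**
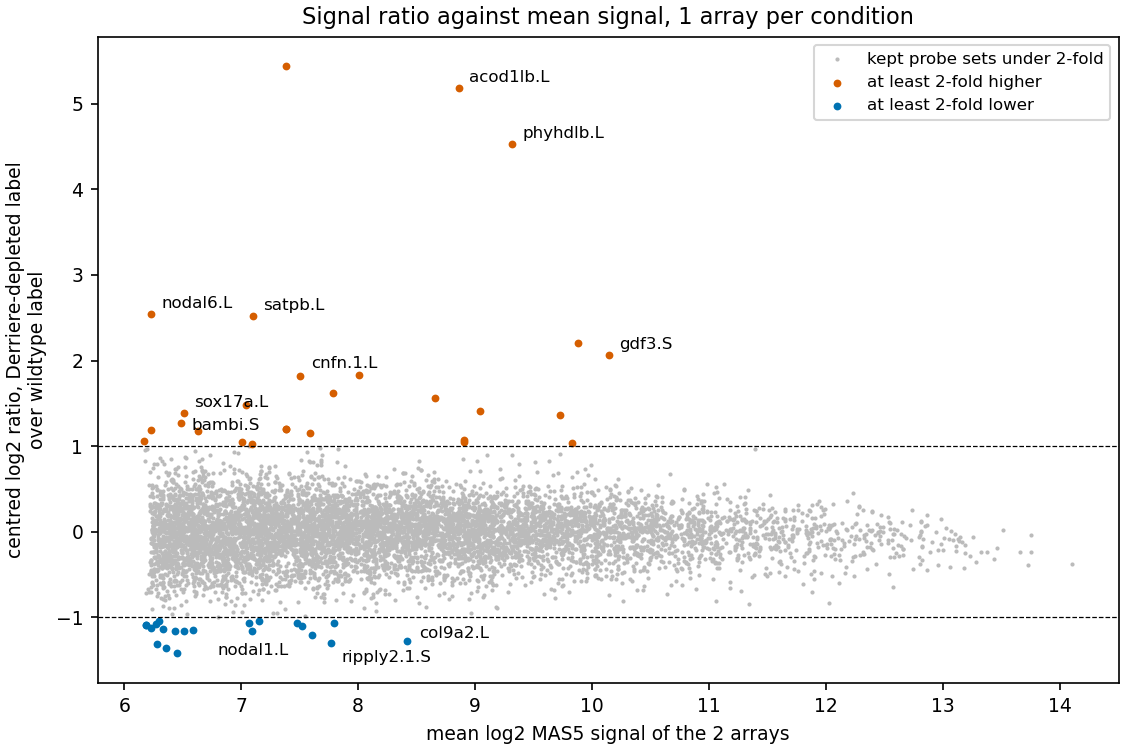
The horizontal axis is the mean log2 signal of the arrays and the vertical axis the centred log2 ratio of the array labelled Derriere depleted over the array labelled wildtype, with 1 point for each of the 7747 kept probe sets. Orange points are the 27 at least 2-fold higher and blue points the 21 at least 2-fold lower, and acod1lb.L, phyhdlb.L, satpb.L, nodal6.L and gdf3.S stand above 2 on the log2 scale.

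The highest named genes were acod1lb.L and phyhdlb.L. The transcript of acod1lb.L, named for similarity to aconitate decarboxylase, the itaconate-forming enzyme of activated macrophages, read 77.1 in the array labelled wildtype and 2812.5 in the array labelled Derriere depleted, a 36.3-fold difference. The transcript of phyhdlb.L, named for a phytanoyl-CoA dioxygenase domain, read 132.2 and 3077.5, a 23.1-fold difference. The gene satpb.L was 5.73-fold higher, from 57.2 to 329.6. These 3 genes lie within 5 consecutive genes of the Xenopus_laevis_v10.1 assembly, used here for neighbourhood only. Each has near-identical copies by name, so the share of the signal that belongs to each copy is uncertain.

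Ligands and modulators of TGF-beta signalling held 4 of the genes past 2-fold, 3 higher and 1 lower. Besides gdf3.S, the Nodal-related ligand nodal6.L was 5.83-fold higher in the array labelled Derriere depleted, from 31.0 to 182.0, and bambi.S, a pseudoreceptor that dampens BMP signalling, was 2.40-fold higher, from 57.6 to 139.3. The ligand of left-right asymmetry nodal1.L was 2.07-fold lower, from 203.5 to 99.1. The 31 measured genes of the TGF-beta, Nodal and BMP list had a median log2 ratio of 0.03, at percentile 67.04 of 10000 random lists matched on signal. Their mean of 0.19 lay at percentile 99.59. That mean includes gdf3.S at 2.06 and nodal6.L at 2.545, the largest ratios of the list, while 16 of its genes were above 0 and 15 below. The mean is thus no sign of a shift of the list as a whole. The nodal6 genes are repeated near-identical copies, and the value of nodal6.L dropped to 1.98 on the log2 scale with the added constant, while nodal1.L came to less than 2-fold there.

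The endoderm transcription factors sox17a.L and sox17b.1.S were both higher. The signal of sox17a.L was 56.2 in the array labelled wildtype and 147.8 in the array labelled Derriere depleted, a log2 ratio of 1.39. The value of sox17b.1.S was 1.14 over 2 probe sets that read 0.80 and 1.48, and it came to less than 2-fold, at 0.96, with the added constant. The other 5 measured genes of the endoderm list ranged from -0.08 to 0.13, with a median of 0.09 and an SD of 0.09. The list of 7 had a median of 0.10 at percentile 82.73.

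The remaining genes of the 12 highest ranged from 1.19 to 1.81 on the log2 scale. They were the cornified envelope gene cnfn.1.L at 1.81, the endosomal sorting gene snx2.S at 1.63, the platelet-activating factor receptor gene ptafr.L at 1.36, the cement gland gene ag1.S, which was 2.30-fold higher, and the mannosyltransferase gene dpm1.L at 1.19. A brighter probe set of the homeolog ag1.L, with a mean log2 signal of 9.29, read 0.10, so the cement gland gene did not rise in both copies. The log2 ratio of ag1.S was 0.59 without the signal filter, which brings in a dim second probe set, and that of dpm1.L was 0.94 with the added constant.

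Regulators of posterior mesoderm differed little. The T-box genes tbxt.S and tbx6.L had log2 ratios of 0.16 and 0.10, msgn1.L, a regulator of presomitic mesoderm, read 0.21, and the caudal homeobox gene cdx4.L read -0.02. The BMP-responsive homeobox repressors ventx2.1.L at 0.81 and ventx2.1.S at 0.65 had the highest values in the list, followed by cdx1.S at 0.44. Of 15 measured genes 12 were above 0 and 0 were past 2-fold. The list median of 0.16 lay at percentile 97.59, and it stayed in the upper tail in 7 of 12 alternatives, with a lowest percentile of 91.66 under a stricter signal filter.

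Somite segmentation genes were divided. The segment border repressor ripply2.1.S was 2.46-fold lower in the array labelled Derriere depleted, from 341.8 to 139.6. The brighter ripply2.2.S did not fall with it and read 0.07, from 475.1 to 502.5. The bHLH factor mespa.S, active in the anterior presomitic mesoderm, read -0.68 and the Notch-responsive repressor hes5.10.L read 0.62. Of 22 measured genes, 1 was past 2-fold, 10 were above 0 and 12 below, and the median of -0.07 lay at percentile 23.28.

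Most measured genes of the skeletal muscle list had negative log2 ratios. Of 27 measured genes 20 were below 0, 7 were above 0 and 0 were past 2-fold. The lowest were the troponins tnnt3.S at -0.78 and tnnc2.S at -0.68, the tropomyosin tpm1.L at -0.68 and the fast myosin light chain mylpf.L at -0.67. The myogenic factor genes myod1.S and myf5.L read 0.07 and -0.09. The list median of -0.15 lay at percentile 1.62.

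Notochord and organizer genes had a median log2 ratio of -0.21 over 11 genes, 10 of them below 0, at percentile 4.74. The organizer gene chrd.1.S is not among the 11, because its symbol did not match the list entry chrd. It read 0.09 over 2 probe sets. The lowest were lhx1.L at -0.80, foxa4.S at -0.73 and the collagen col9a1.L at -0.41, while the homeolog foxa4.L read -0.195. Another collagen IX gene, col9a2.L, was 2.41-fold lower, from 529.3 to 220.6. In the extracellular matrix list, to which it belongs, col8a1.S read -0.84, and the 32 genes had a median of -0.09 at percentile 6.21. As a mean, the notochord list read -0.29 at percentile 0.40 and the matrix list -0.12 at percentile 1.38. The direction of the matrix list was not stable, since its median was 0.02 at percentile 68.08 under the stricter signal filter and 0.00 at percentile 50.64 without a filter.

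**Figure D2:**
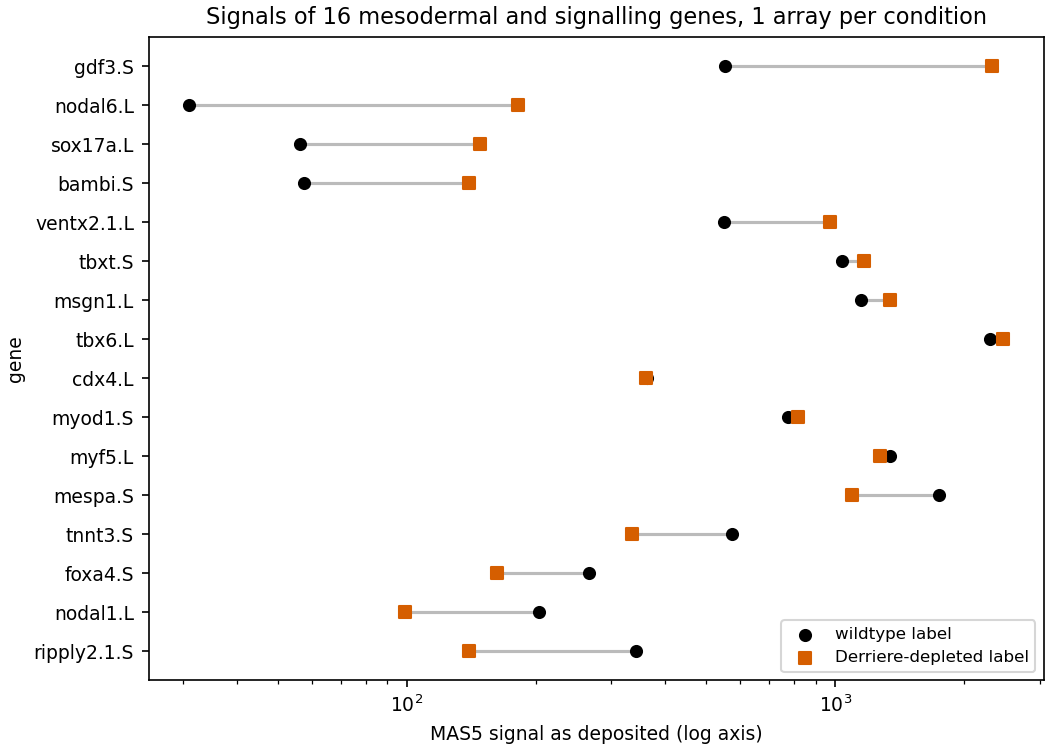
The horizontal log axis is the deposited MAS5 signal of 16 mesodermal and signalling genes in the array labelled wildtype (black circles) and the array labelled Derriere depleted (orange squares), with a line joining both values of a gene. The squares of gdf3.S and nodal6.L lie far to the right of the circles, at 2318.6 against 552.0 and at 182.0 against 31.0, while nodal1.L and ripply2.1.S lie to the left and cdx4.L, myod1.S and tbx6.L nearly coincide.

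The other 7 lower genes past 2-fold under the naming rule were named from no list, and 1 more lower gene had a clone name. The 7 were commd2.L at -1.42, mknk1.S, a kinase that phosphorylates a translation initiation factor, at -1.36, the acyl-CoA binding gene dbi.S at -1.16, cdkn2aip.L at -1.15, the matricellular gene ccn2.L at -1.13, lysmd4.L at -1.10 and the fatty acid elongation gene hacd1.L at -1.07. Without the signal filter mknk1.S read -0.76 and ccn2.L read -0.72, and with the added constant ccn2.L, cdkn2aip.L, lysmd4.L and hacd1.L ranged from -0.91 to -0.99. Of the 23 named genes past 2-fold, 14 stayed past it in every alternative setting that measured them.

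Epidermal genes had positive log2 ratios in the array labelled Derriere depleted. Of 32 measured genes 25 were above 0 and 0 were past 2-fold. The list median of 0.20 lay above those of all 10000 random lists. The epithelial cadherin cdh1.S read 0.95, the homeobox gene dlx3.L 0.63 and the grainyhead factor grhl1.L 0.59. The keratin krt12.4.L read 0.48 and its homeolog krt12.4.S -0.15, and the abundant secreted lectin itln1.L read -0.24. The list of ionocyte and multiciliated cells, with 4 measured genes, had a median of -0.02 at percentile 45.92.

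Neural plate and neuron genes had a median log2 ratio of -0.14 over 32 genes, 22 of them below 0, at percentile 1.68. The neural progenitor factor sox2.L read -0.60 and the synaptic gene snap25.L -0.55. The median left the lower tail with the stricter signal filter, at percentile 9.97, and sox2.L read -0.28 without the filter. Neural crest genes had a median of -0.01 over 16 genes at percentile 44.78.

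**Figure D3:**
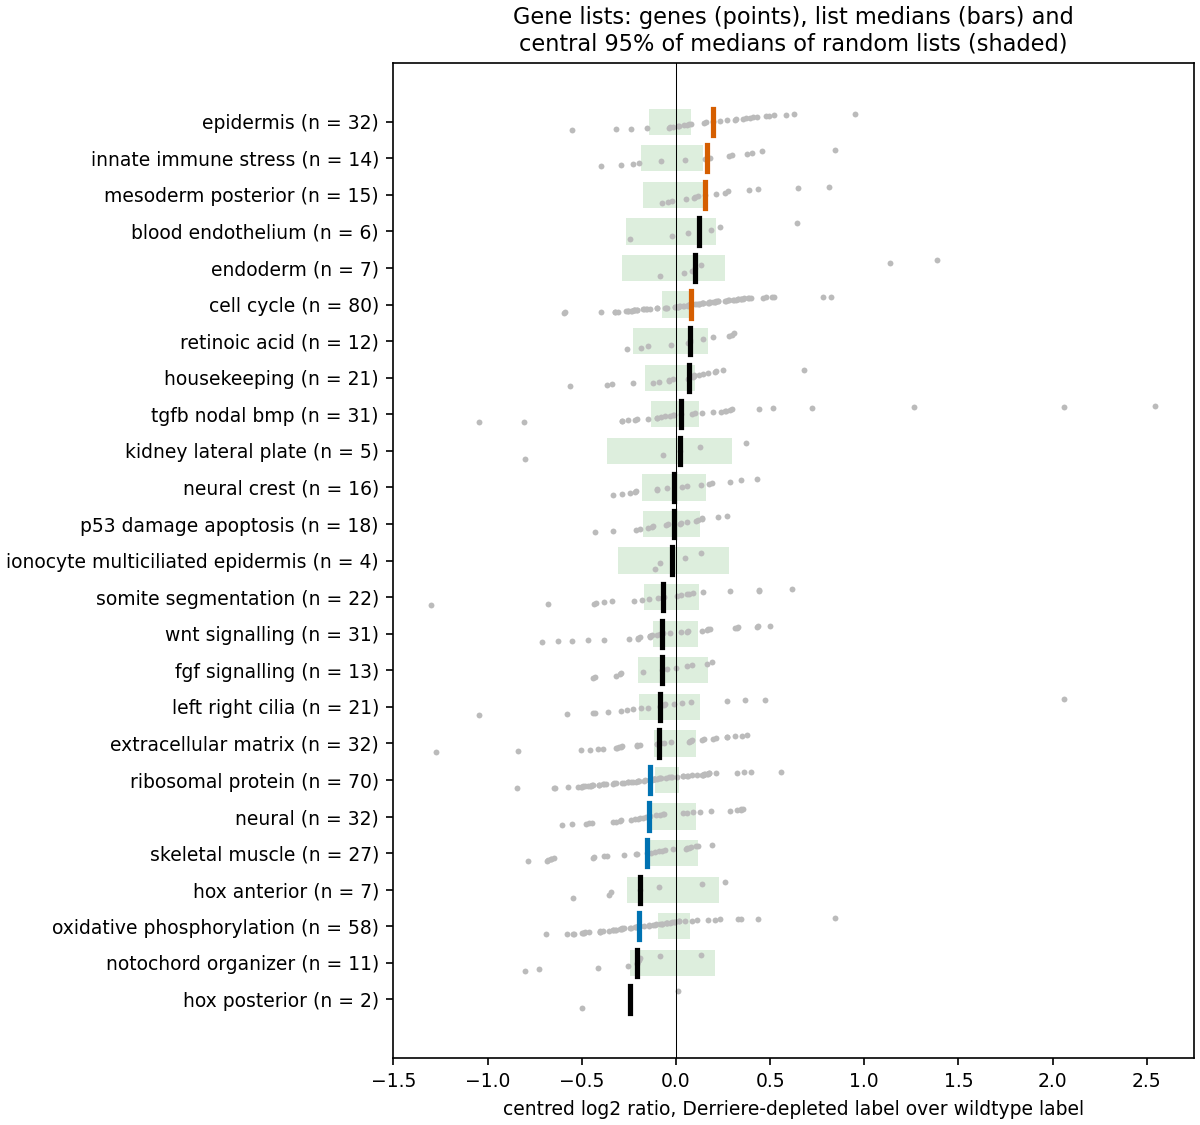
Each row is 1 of 25 gene lists, with the number of measured genes in brackets, and the horizontal axis is the centred log2 ratio of the array labelled Derriere depleted over the array labelled wildtype. Points are genes, bars are list medians (orange in the upper tail, blue in the lower tail) and shading spans the medians of random lists between both tails; epidermis at 0.20 and oxidative phosphorylation at -0.20 lie farthest outside the shading.

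The Wnt, FGF and retinoic acid lists lay between the tails of random lists. The Wnt list had a median of -0.07 over 31 genes at percentile 11.63, with wnt5b.S at -0.71. The beta-catenin gene ctnnb1.S read 0.50 and its homeolog ctnnb1.L 0.06. The FGF list had a median of -0.07 over 13 genes at percentile 25.64, with fgf8.L at 0.00. The retinoic acid list had a median of 0.07 over 12 genes at percentile 82.65, with the degrading enzyme gene cyp26a1.L at 0.31, and its median reached percentile 99.01 under the stricter signal filter, which left 5 genes.

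The list of left-right and cilium genes had a median of -0.08 over 21 genes, 15 of them below 0, at percentile 23.01. It held gdf3.S and nodal1.L, and the ciliary dynein gene dnai1.L read -0.58. The left-right antagonists dand5.S, at 79.6 in the array labelled wildtype and 51.4 in the array labelled Derriere depleted, and lefty.L, at 40.9 and 22.0, were under the signal filter. The list of Hox genes of paralogous groups up to the eighth, anterior and trunk together, had a median of -0.19 over 7 genes at percentile 8.36, with hoxb4.S at -0.54; hoxa7.L, hoxb7.L, hoxc6.S and hoxc8.S of the trunk were 4 of the 7. Only 2 posterior Hox genes passed the filter, with a median of -0.24 and no percentile.

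Genes of growth and metabolism shifted by small amounts across many members. Oxidative phosphorylation genes had a median log2 ratio of -0.20 over 58 genes, 46 of them below 0. That median lay below those of all 10000 random lists. The lowest member was the complex III subunit gene uqcrq.S at -0.69, while the ratio largest in size was positive, atp5pd.S at 0.84. Ribosomal protein genes had a median of -0.14 over 70 genes, 49 below 0, at percentile 0.37, with rpl34.L at -0.84, or -0.42 without the signal filter. Cell cycle genes had a median of 0.08 over 80 genes, 52 above 0, at percentile 98.74. The mitotic survivin genes birc5.L and birc5.S read 0.83 and 0.78, while stmn1.S and ccna2.S both read -0.59. None of these lists had a member past 2-fold. Measures of RNA and labelling differed between the arrays as well: the ratio of 3' to 5' signal was 4.74 in the array labelled wildtype and 3.54 in the array labelled Derriere depleted for beta-actin, 32.3 and 24.3 for Gapd, 206.5 and 126.3 for a3Act and, in the other direction, 65.3 and 71.6 for a1Act, and the 24 poly-A control probe sets had a median log2 ratio of -0.79.

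The innate immune and stress list had a median of 0.17 over 14 genes, 9 above 0, at percentile 98.79, with the complement gene c3.L at 0.85 and the chaperone gene hsp90ab1.S at 0.46. The median was 0.00 at percentile 52.96 without the signal filter. The p53 and apoptosis list had a median of -0.01 over 18 genes at percentile 50.85. Blood and endothelial genes read 0.12 over 6 genes at percentile 87.35, and kidney and lateral plate genes 0.02 over 5 genes at percentile 65.66. Genes often used as internal references read 0.07 over 21 genes at percentile 90.47, with odc1.L at -0.04 and up to 0.03 in the alternatives. The members of that reference list were not all flat, and ranged from ppia.S at -0.565 to slc35b1.L at 0.68. Of the 24 lists with a percentile, 4 lay in the upper tail and 4 in the lower, against 1.2 for lists of randomly drawn genes. Members of a list can vary together, unlike randomly drawn genes, so the 1.2 cannot serve as a test of an excess.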

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

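The tests in this part were chosen after the results were seen. The control probe set for EGFP, outside the comparison, carried signal in the array labelled wildtype. It read 72.7 there and was under the floor of 19.7 in the array labelled Derriere depleted, so it was at least 3.69-fold higher in the array labelled wildtype. At the deposited signals, without the floor, it was 7.27-fold higher there, a size that rests on a reading under the floor. Of 3972 probe sets for frog transcripts of like mean signal, 2 differed by 7.27-fold or more in either direction. How many differed by 3.69-fold or more was not counted. Other control probe sets for sequences foreign to the frog were lower in the array labelled Derriere depleted too. Of the 12 poly-A control probe sets whose mean signal reached the floor 11 were lower, and the 12 had a median of 1.86-fold lower and went up to 2.94-fold. Several of these probe sets read the same transcript (dap, lys, phe or thr), so they are not independent controls. The DsRed1 probe set, at 13.3 and 6.00, and the AsRed2 probe set, at 16.5 and 13.1, were under the floor in both arrays and give no direction.

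The derriere transcript itself was 4.17-fold higher in the array labelled Derriere depleted. The lowest log2 ratio of gdf3.S over the alternatives was 2.02. These could hardly lower it, because both readings lay far above the floor and the arrays had similar median signals. All of them started from the deposited signals, so the scaling and background steps of MAS5 itself were not tested. Swapped array labels could place both the lower derriere signal and the EGFP signal in the injected embryos, if the GFP given with the morpholino was a transcript that this probe set reads. The EGFP reading of 72.7 rests on 1 probe set that falls short of the signal filter, the poly-A controls moved the same way, the labels do not say whether control embryos received GFP or in what form and variant it was injected, and with 1 array per group a swap cannot be told apart from the labels being right. A rise or stabilisation of the derriere transcript under the morpholino may also give the pattern and was not tested.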

How the results depend on the processing

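The alternatives were planned except matching by synonym and counting probe sets that name both homeologs, which were added after the data were seen. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. The targeted gene stayed between 2.02 and 2.07 on the log2 scale, and of 63 named genes checked 2 changed sign, fgf8.L (-0.03 to 0.01) and odc1.L (-0.07 to 0.03). Centring moved no setting's median by more than 0.0142. All 48 probe sets past 2-fold stayed so without the floor, with the higher floor, without centring, with loess and without the filter. Removing the floor changes no kept ratio, since no kept probe set was at it, and removing the filter mainly adds probe sets. Those settings are therefore no check of stability. With quantile normalization 47 stayed, with the added offset 29, and with the 75th percentile filter, which tests fewer probe sets, 13.

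Counts of higher and lower probe sets, 27 and 21, became 22 and 7 with the offset, 55 and 81 without the filter, 12 and 1 with the stricter filter, 195 and 262 at 1.5-fold, and 10 and 0 at 3-fold. Counts of genes, 17 and 11, became 13 and 5, 27 and 33, 6 and 1, 91 and 140, and 8 and 0 in the same order. The offset shrinks ratios of dim probe sets by construction, and the filters and thresholds change what is counted.

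The posterior mesoderm median left the upper tail with quantile normalization (0.155, percentile 97.19), loess (0.158, 97.44), no filter (0.112, 97.02), the stricter filter (0.113, 91.66) and both homeologs counted (0.156, 97.05). The immune and stress list left it without the filter (0.000, 52.96) and as a mean (0.132, 96.18), and the neural list left the lower tail with the stricter filter (-0.100, 9.97) and as a mean (-0.111, 4.55). The notochord list entered the lower tail without the filter (-0.075, 0.23), with the stricter filter (-0.300, 2.48) and as a mean (-0.286, 0.40). Retinoic acid with the stricter filter (0.277, 99.01), and TGF-beta (0.187, 99.59) and endoderm (0.401, 99.89) as means, entered the upper tail, and matrix as a mean (-0.117, 1.38) and anterior and trunk Hox by synonym (-0.268, 1.46) the lower. The matrix median was 0.019 (68.08) with the stricter filter. The cause was not tested. Muscle, epidermis, cell cycle, ribosomal protein and oxidative phosphorylation kept their tails in all 12 alternatives. Signal over background limits the dim genes: the robust SD of the log2 ratio was 0.349 in the lowest of 4 equal signal bins and 0.244 in the highest.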

Other observations

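All tests of explanations in this part were chosen after the results were seen. Some of the largest differences belonged to probe sets without a gene name. The highest of them read 25.2 in the array labelled wildtype and 1101.3 in the array labelled Derriere depleted. In the main setting this was a 43.4-fold difference and above any named gene. The reading of 25.2 lay near the floor, so the size and the rank are uncertain. The added offset, which shrinks ratios with a dim reading, was not reported for this probe set. Another read 437.4 and 2038.2, a log2 ratio of 2.21. The lowest such probe sets had log2 ratios of -1.31 and -1.16. In all, 17 of the 48 probe sets past 2-fold had no gene or several genes.

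The copies of a gene from the long and short subgenomes tended to move together. Over 524 homeolog pairs measured on both sides, the log2 ratios had a Pearson r of 0.38 and a Spearman rho of 0.34 across genes, which are not independent replicates. Of the 83 pairs with a member at 0.5 or more in size, 69 had the same sign. Probes that read both copies would give the same sign too.

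Control transcripts also differed between the arrays. The 24 poly-A control probe sets had a median log2 ratio of -0.79 at the deposited signals, with 19 lower and 5 higher in the array labelled Derriere depleted and a range of -1.56 to 2.11. Many were dim: over the 12 whose mean signal reached the floor, the median was -0.89 and 11 were lower. The 18 hybridisation control probe sets had a median of -0.21, with 16 lower. In both kinds of control several probe sets read the same transcript, so these counts are not of independent controls.

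The genes acod1lb.L, phyhdlb.L and satpb.L neighbour each other, and they were the only 3 measured genes among the 25 within 10 places of them in the Xenopus_laevis_v10.1 assembly. In 17 of 10000 random draws of 28 measured genes there were as many close pairs. The neighbourhood was noticed in these same genes before the draws were made, so this count describes how unusual it is and does not exclude chance. A general immune and stress response may be involved, but the evidence is not stable. The immune and stress list median of 0.167 lay in the upper tail of random lists and lost it in 2 of 12 alternatives, and its members are far below the shift of the cluster. A difference between the clutches or haplotypes of the embryos, and signal shared between near-identical copies, were not tested and stay open.

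Muscle and neural medians were negative and the epidermal median positive, as could follow from what each dissected piece held. With a smaller share of muscle alone, other tissues would gain alike. In these arrays they did not, since the epidermal median exceeded the neural one by 0.340, and by at least 0.180 in every alternative. The joint SD of random list medians, 0.084, covers spread between genes and not between dissections or labelling reactions. With 1 array per group the difference therefore cannot decide whether the share of muscle alone differed. More epidermis remains open. The 5 brightest epidermal genes, themselves part of the list, had a median of 0.041 against the list median of 0.196. Their SD of 0.183 is a spread between genes and not between dissections, so this comparison cannot decide it. A change in cell fate after depletion was not tested and cannot be separated from dissection with 1 array per group. The 3' to 5' ratios and the poly-A controls also differed between the arrays, and their bearing on these medians was not tested.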
